A study of Mus musculus with 12 samples.

How the data were processed

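RNA was measured on 12 Affymetrix whole-transcript arrays, 1 per sample, in 4 groups of 3. The samples were mouse CD4+ T cells with Lat (Lat+) or without it (Lat-), kept for 4 h either unstimulated or with antibodies against CD3 and CD28. Groups and replicate numbers came from the sample titles, and the design text calls the 3 samples of a group biological replicates.

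The deposited table holds log2 expression values for 35556 probe sets on each array, and per the submitters' processing notes the authors made it with RMA (robust multi-array average: background correction, quantile normalization and a summary over probes) and the affy package. Their versions, the probe set definition file and a genome build were not given in the sources used here, so no coordinates are printed. Scanner files were not used here. The values ran from 1.64 to 14.06, and the array medians lay between 5.29 and 5.38. Array 3 of resting Lat- cells had a narrower range, with quartiles of 4.05 and 7.76. The quartiles were 3.89 and 7.95 on array 1 and 3.90 and 7.98 on array 2 of that group. Array 3 also had the lowest correlations within any group, 0.992 with array 1 and 0.991 with array 2. RMA forces the arrays to nearly the same distribution, so a change of total RNA per cell would not be seen. Low values hold background signal and understate fold changes of dim genes, and no detection calls were used here, so a fold against a level below the array medians is given as a lower bound. For arrays, the number of samples limits the precision: with 3 per group the median standard error of a log2 difference between groups was 0.12, and that of the difference between responses was 0.17.

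Probe sets were named from the platform annotation supplied with the values. Of the 35556 probe sets, 21218 had 1 gene symbol, 1881 had several and 12457 were not listed there. Identifiers of 21185 of the 21218 were found in the reference gene table (assembly GRCm38.p6, used for names alone), which changed 0 symbols. Only probe sets with 1 symbol were tested. For the 1386 genes with more than 1 probe set, the probe set with the highest mean over the 12 arrays stood for the gene, which left 18820 genes, and no dim gene was left out. Which exons the Lat probe set covers, relative to the deleted part of the gene, was not given in the sources used here.

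The log2 values were fitted as deposited with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per group over all 12 arrays, so that the groups shared 1 estimate of the spread. There were 5 comparisons: activation in Lat+ cells, activation in Lat- cells, Lat- against Lat+ cells at rest, the same after activation, and the difference between both activation responses (the interaction). P-values were adjusted over all genes of a comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Every adjusted p given for a gene comes from this limma fit, and errors of differences are its standard errors. P-values measure the spread between samples within groups, pooled over the 4 groups and moderated over genes, not that of 1 group alone. Resting Lat- arrays varied more: the SD of the differences between 2 arrays was 0.278 to 0.343, against 0.207 to 0.255 in the other groups. The pooled spread may therefore be too small for comparisons that use them. Values were read with the data.table package, version 1.17.8, and plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

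The sample groups, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The rule named Lat first, then Cd5, Cd6, Cd69, Lcp2 and Zap70 whether called or not. It added per comparison the 10 called genes with the largest change in each direction, provided that all 3 values of one group lay beyond all 3 of the other (a call was enough for the interaction). From each gene list with a camera call or with at least 3 called members it added up to 4 called members with the largest change, and from a list with none called the member with the smallest p. Gene models without a proper name and members of families of near-identical copies are named as uncertain.

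The 31 gene lists covered T cell receptor signalling and its target genes, activation receptors, cytokines, metabolism, stress, the cell cycle, T cell subsets and cell types that a CD4+ sort could hold by mistake. Of the 631 distinct list genes, 577 were measured. Foxp3, the regulatory T cell transcription factor gene, was only on probe sets with several symbols and was not tested. Each list was tested against all other genes with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the data was run as an alternative, as was fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. Lists overlap: 8 of the 15 measured regulatory T cell markers were also in another list.

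The replicate numbers were tested for pairing by correlating, over genes, the deviations of same-numbered arrays from their group means. The 3 correlations lay between 0.124 and 0.344 for activation in Lat+ cells, 0.157 and 0.317 for Lat- against Lat+ cells after activation, 0.0794 and 0.269 for activation in Lat- cells, and -0.0115 and 0.374 at rest. In all 4 groups the number-1 arrays carried both Xist and Y-linked transcripts, the number-2 arrays Y-linked transcripts alone and the number-3 arrays Xist alone, so same-numbered arrays shared the sex makeup of their mice. The numbers were therefore treated as possible pairs in every comparison, though at rest only 1 of 3 arrays correlated best with its own number. The main fit leaves the numbers out, and the fit with the replicate number as a block is given as an alternative. With the block 169 rather than 116 genes were called for activation in Lat- cells, and 496 rather than 369 at rest. The labels do not say what a number shares, and the Xist and Y-linked pattern was weighed after the fits with and without the block had been seen.

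The fits were tested on simulated data made from the means of resting Lat+ cells and the fitted spreads of the 18820 genes. For activation in Lat- cells, 46.3% of genes changed by 0.5 (log2) were recovered, and 100% of those changed by 1 or by 2. For Lat- against Lat+ cells at rest, 55.2%, 98.5% and 100% were recovered at these sizes. There were 9 false calls among 173 for activation in Lat- cells and 3 among 172 at rest. A response simulated at a ratio of 0.25 came out with a slope of 0.242. For activation in Lat- cells a shifted list had a camera adjusted p of 3.23e-17, and 0 of 30 other lists were called. The simulated genes varied independently of each other, so false list calls from genes that move together were not tested. Every simulated group had the same spread and same-numbered arrays had no link, as the fit assumes. The rates of recovery and of false calls are therefore not shown for real comparisons with the more variable resting Lat- arrays.

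Alternatives changed 1 choice at a time: quantile normalization between the arrays, centring on array medians, leaving out the lowest tercile of genes by mean level or those below the median level, other rules for several probe sets of a gene, an intensity trend with a robust prior, array weights, the replicate number as a block, a fit on only the compared groups, stricter thresholds, and leaving out each array in turn. Leaving out the 4 arrays numbered 1 together was added after the data had been seen.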

Results

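Transcript levels were compared in CD4+ T cells of mouse lymph nodes and spleen that either kept or had lost Lat, the membrane adaptor that links the T cell receptor to its downstream signalling proteins. The mice carried a floxed Lat allele with an hDTR reporter and the Tmat-Cre transgene, and reporter-positive cells were sorted as Lat+ and reporter-negative cells as Lat-. Both were sorted as CD5+, CD62L+ cells without CD25, CD69, CD8, the gamma-delta receptor or lineage markers. Each kind was kept for 4 h at rest or activated for 4 h through CD3 and CD28, with 3 arrays in each of the 4 groups. Array medians lay between 5.29 and 5.38 (log2), and Pearson correlations over the tested genes between arrays of 1 group were 0.991 to 0.997. The first principal component held 76.8% of the variance and set activated Lat+ cells (77.2 to 78.6) apart from the other 3 groups (-32.5 to -19.8). Group means of activated Lat+ cells correlated with those of the others at 0.951 to 0.957, while the other 3 groups correlated with each other at 0.996 to 0.997.

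Lat itself followed the sort. Its log2 level was 10.38 ± 0.31 (SD, n = 3) in resting and 10.53 ± 0.26 (SD, n = 3) in activated Lat+ cells, against 7.42 ± 0.10 (SD, n = 3) in resting and 7.38 ± 0.36 (SD, n = 3) in activated Lat- cells. It was 7.79-fold lower in Lat- cells at rest (log2 difference -2.96, SE 0.19, limma adjusted p = 2.27e-06) and 8.85-fold lower after activation (-3.15, SE 0.19, limma adjusted p = 6.96e-09). Activation gave log2 differences of 0.14 in Lat+ cells (limma adjusted p = 0.622) and -0.04 in Lat- cells (limma adjusted p = 0.978), and their difference was -0.18 (limma adjusted p = 0.675). The signal that remained in Lat- cells at rest was 12.8% of that in Lat+ cells. Which part of the transcript the probe set reads, relative to the deletion, is not given in the sources used here.

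Activation of Lat+ cells addressed the full response of cells with the adaptor. Secreted factors were among the genes that rose most: the chemokine gene Ccl3 by 6.70 (log2, SE 0.24, limma adjusted p = 6.74e-11), the T cell growth factor gene Il2 by 6.49 (SE 0.19, limma adjusted p = 2.44e-11) and the chemokine gene Xcl1 by 5.67 (SE 0.18). Bcat1, an enzyme of branched-chain amino acid breakdown, rose by 6.04 (SE 0.15), the transcription factor gene Irf8 by 5.91 (SE 0.17) and Sema7a, a membrane semaphorin, by 5.94 (SE 0.20). Among genes that fell were Il7r, the receptor for the survival cytokine IL-7 (-3.55, SE 0.19), S1pr1, the receptor that lets lymphocytes leave lymph nodes (-3.51, SE 0.11), and Pik3ip1, an inhibitor of PI3-kinase (-3.41, SE 0.13). Ccl3 and Bcat1 lay below every array median at rest, so their rises are lower bounds. All 3 arrays of one group lay beyond all 3 of the other for each of these genes. In all, limma called 3494 genes higher and 3875 lower of 18820 tested, of which 1454 and 1269 changed at least 2-fold.

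By gene group, several lists moved in 1 direction in activated Lat+ cells. All 24 measured NFAT-linked genes rose (24 adjusted over the list alone), with a median of 3.49 (camera adjusted p = 2.41e-15 and adjusted p = 0.103 with an estimated correlation). All 40 ribosome biogenesis genes rose (40 adjusted over the list alone), such as Rrp1b by 3.71 (SE 0.14) and Grwd1 by 3.58 (SE 0.13), with camera adjusted p = 3.8e-32 and adjusted p = 0.093 with an estimated correlation. Of 26 cytokine and chemokine genes 19 rose (19 adjusted over the list alone, camera adjusted p = 3.52e-09 and adjusted p = 0.103 with an estimated correlation). Of 27 activation surface genes, a list that holds receptors and some ligands, 22 rose (23 adjusted over the list alone, camera adjusted p = 1.45e-13 and adjusted p = 0.141 with an estimated correlation). Members that rose included the TNF-family ligand gene Tnfsf14 (4.59, SE 0.17), the transferrin receptor gene Tfrc (4.16, SE 0.26) and Tnfrsf9, which encodes the costimulatory receptor 4-1BB (4.11, SE 0.24). The rise of Tnfsf14 is a lower bound, from a resting level below every array median. Of 28 genes of naive and quiescent cells 24 fell (26 adjusted over the list alone, camera adjusted p = 1.45e-13 and adjusted p = 0.093 with an estimated correlation). One of them was Txnip, an inhibitor of glucose uptake (-3.06, SE 0.12).

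Metabolic genes rose in most members of their lists in activated Lat+ cells. Of 26 genes of amino acid transport and the ATF4 response 23 rose and 1 fell (23 and 1 adjusted over the list alone, camera adjusted p = 1.33e-12 and adjusted p = 0.141 with an estimated correlation). The asparagine synthetase gene Asns was higher by 3.66 (SE 0.21). Of 18 cholesterol biosynthesis genes 14 rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 1.52e-06 and adjusted p = 0.207 with an estimated correlation). The squalene epoxidase gene Sqle was higher by 3.02 (SE 0.15). Of 18 glycolysis genes 13 rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 7.72e-05 and adjusted p = 0.203 with an estimated correlation). Among them were hexokinase Hk2, higher by 4.06 (SE 0.12), and Pdk1, a kinase that restrains pyruvate oxidation, lower by -1.91 (SE 0.09). Of 17 genes of the unfolded protein response 10 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 6.31e-06 and adjusted p = 0.093 with an estimated correlation). Of 10 heat shock genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.000363 and adjusted p = 0.103 with an estimated correlation). Hspd1 was among those that rose (2.63, SE 0.10). Of 16 p53 target genes 11 rose and 1 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.000272 and adjusted p = 0.203 with an estimated correlation). The cell cycle inhibitor Cdkn1a was higher by 4.35 (SE 0.34). The rises of Asns and Hk2 are lower bounds, from levels below every array median.

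Early signalling targets and regulators rose in part in activated Lat+ cells. Of 24 immediate early genes 14 rose and 1 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.00425 and adjusted p = 0.657 with an estimated correlation). Myc was higher by 3.15 (SE 0.37) and Egr1 by 2.56 (SE 0.34). As a measured fact beside this group, the immediate early genes were higher on the array numbered 1 of each group than on the mean of its other 2 arrays, by 0.95 in resting Lat+ cells, 1.05 in resting Lat- cells, 0.97 in activated Lat- cells and 0.30 in activated Lat+ cells. Of 15 RAS-MAPK feedback genes 12 rose (12 adjusted over the list alone, camera adjusted p = 6.31e-06 and adjusted p = 0.19 with an estimated correlation), led by the RAS pathway inhibitor gene Spry1 (4.85, SE 0.34). Of 25 NF-kappaB-linked genes 11 rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.00519 and adjusted p = 0.653 with an estimated correlation). Tnf was higher by 4.11 (SE 0.52). Of 32 negative regulators of receptor signalling 18 rose and 8 fell (19 and 8 adjusted over the list alone, camera adjusted p = 0.0169 and adjusted p = 0.653 with an estimated correlation). Quantile normalization and leaving out the lowest tercile of genes each ended that last call (camera adjusted p = 0.0507 and 0.0625). Of 25 helper T cell transcription factor genes 13 rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.00138 and adjusted p = 0.306 with an estimated correlation). Tbx21, which encodes T-bet, was higher by 3.07 (SE 0.24).

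Other groups moved both ways in activated Lat+ cells. Of 53 genes of the receptor signalosome 13 rose and 27 fell (13 and 28 adjusted over the list alone, camera adjusted p = 0.0731, and 0.0211 after quantile normalization). The kinase gene Zap70 rose by 1.49 (SE 0.10) and the adaptor gene Lcp2 by 0.76 (SE 0.09), while the adaptor gene Fyb fell (-2.35, SE 0.12), as did Grap2 (-1.95, SE 0.09). The surface receptor genes Cd5 and Cd6 rose by 1.32 (SE 0.11) and 1.24 (SE 0.10), and the early activation marker Cd69 rose by 1.84 (SE 0.35, limma adjusted p = 0.000527). Of 30 cell cycle genes 6 rose and 9 fell (6 and 10 adjusted over the list alone, camera adjusted p = 0.923). Cdk6 was higher by 2.83 (SE 0.16) and Ccnd3 lower by -1.39 (SE 0.09). Of 31 interferon-stimulated genes 8 rose and 11 fell (8 and 11 adjusted over the list alone, camera adjusted p = 0.724). Gbp2 was higher by 2.25 (SE 0.19) and Ifit2 lower by -2.20 (SE 0.13). Of 17 apoptosis regulators 8 rose and 3 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.0477 and adjusted p = 0.485 with an estimated correlation). The survival gene Bcl2l1 was higher by 2.68 (SE 0.15). The camera call for these regulators ended without array 2 of resting Lat+ cells (0.0665), without array 1 of activated Lat+ cells (0.0724), after quantile normalization (0.0931) and without the lowest tercile of genes (0.124). Of 15 hypoxia genes 5 rose and 4 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.975, fry adjusted p = 7.67e-05 downward).

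Markers of other cell types gave no camera call in activated Lat+ cells. The adjusted p was 0.372 for 19 B cell markers (4 higher, 2 lower; 3 and 2 adjusted over the list alone), 0.327 for 26 myeloid markers (1 and 6; 0 and 5 adjusted over the list alone), 0.753 for 13 NK cell markers (4 and 3; 4 and 3 adjusted over the list alone) and 0.883 for 8 gamma-delta and innate-like markers (2 and 1; 2 and 1 adjusted over the list alone). It was 0.883 for 8 erythroid and platelet markers (1 and 0; 1 and 0 adjusted over the list alone) and 0.146 for 12 stromal and endothelial markers (0 and 2; 0 and 2 adjusted over the list alone). Among the members that moved were Pou2af1, a lymphocyte transcriptional coactivator (4.00, SE 0.14), the MHC class II gene H2-Aa (1.18, SE 0.24), the Fc receptor gene Fcgr3 (-2.16, SE 0.15), the granzyme gene Gzmb (3.29, SE 0.21) and the adhesion gene Pecam1 (-2.56, SE 0.10). The changes of H2-Aa, Fcgr3 and Gzmb are lower bounds in size, since their lower level lay below every array median.

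**Figure D1:**
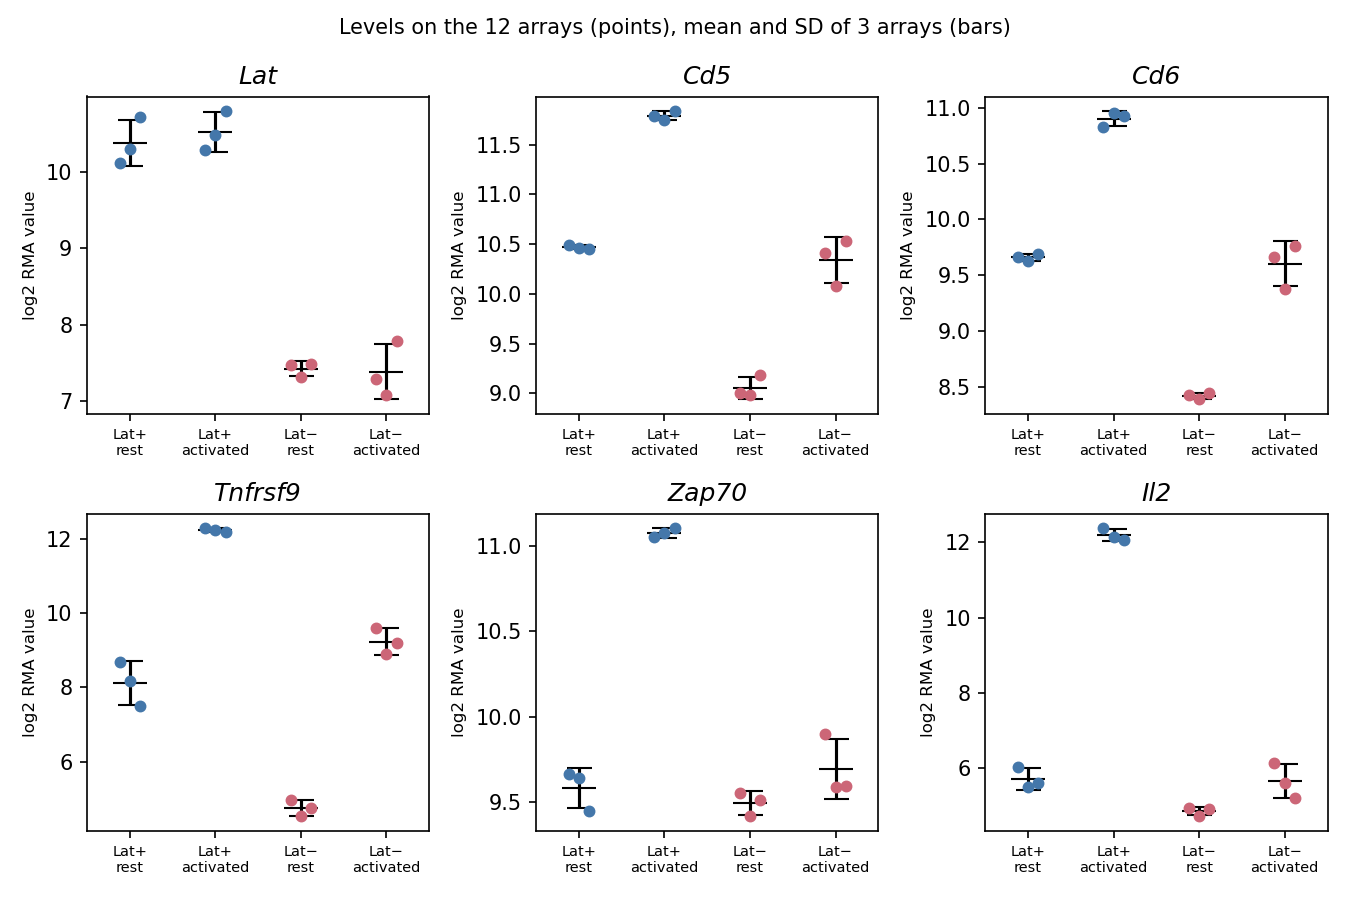
Log2 level of 6 genes on each of the 12 arrays (points), with the mean and SD of the 3 arrays of each group; the vertical axes differ between panels and do not start at 0. Lat lies at 10.38 and 10.53 in Lat+ and at 7.42 and 7.38 in Lat- cells, Cd5 and Cd6 rise in both kinds of cell, and Il2 reaches 12.20 in activated Lat+ cells against 5.65 in activated Lat- cells.

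At rest, Lat- cells had lower levels of 12 of 15 regulatory T cell markers, 17 of 26 effector and memory markers and 10 of 30 cell cycle genes (camera adjusted p = 5.91e-30, 7.07e-30 and 3.06e-26). Cd83 (log2 difference -3.70, SE 0.38, limma adjusted p = 8.77e-05), the regulatory T cell gene Lrrc32 (-3.70, SE 0.42, limma adjusted p = 0.000181), Tnfrsf9 (-3.37, SE 0.24, limma adjusted p = 7.03e-06) and the inhibitory receptor gene Pdcd1 (-3.06, SE 0.16, limma adjusted p = 4.13e-07) were among the lowest relative to Lat+ cells. The chemokine receptor gene Ccr4 (-2.77, SE 0.21) and cyclin A2 (Ccna2, -2.68, SE 0.20) were lower too, as was Klra6 (-2.80, SE 0.42), which is uncertain because it belongs to a family of near-identical receptors. Increases were smaller and included the protease genes Prss12 (1.41, SE 0.19, limma adjusted p = 0.000728) and Pcsk1 (1.36, SE 0.17), the Src-family kinase gene Yes1 (1.31, SE 0.14) and the kinase gene Cdc42bpa (1.07, SE 0.18). For Cd83, Tnfrsf9, Ccr4, Ccna2, Klra6, Yes1 and Cdc42bpa the lower of both levels lay below every array median, so these differences are lower bounds in size. In all, limma called 37 genes higher and 332 lower, of which 5 and 135 differed at least 2-fold, and 2023 genes had an unadjusted p under 0.05. The count of higher genes was 24, 15, 23 and 163 without array 1 or 2 of resting Lat+ or array 2 or 3 of resting Lat- cells, in that order. The count of lower genes was 207 without array 2 of resting Lat+ cells, and without all 4 arrays numbered 1, a choice made after seeing the data, the counts were 8 and 172. With the replicate number as a block 67 genes were higher.

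Of 15 measured regulatory T cell markers 12 were lower in resting Lat- cells (13 adjusted over the list alone), with a median of -1.68 (camera adjusted p = 5.91e-30 and adjusted p = 0.0112 with an estimated correlation). They included the semaphorin co-receptor gene Nrp1 (-2.84, SE 0.29), Ikzf2, which encodes Helios (-2.59, SE 0.42), and Tnfrsf4, which encodes OX40 (-2.24, SE 0.19). Both sorts excluded CD25+ cells and took CD62L+ cells. Of 26 effector and memory markers 17 were lower (21 adjusted over the list alone, median -1.02, camera adjusted p = 7.07e-30 and adjusted p = 0.026 with an estimated correlation). Among them were the IL-2 and IL-15 receptor chain gene Il2rb (-2.58, SE 0.36) and Anxa2 (-2.02, SE 0.24). Of 30 cell cycle genes 10 were lower (16 adjusted over the list alone, camera adjusted p = 3.06e-26 and adjusted p = 0.00118 with an estimated correlation). Among them were the mitotic kinase gene Aurkb (-1.98, SE 0.15) and the topoisomerase gene Top2a (-1.97, SE 0.11), both lower bounds in size because their levels in Lat- cells lay below every array median. Of 27 activation surface genes 13 were lower and 1 higher (16 and 1 adjusted over the list alone, camera adjusted p = 1.61e-18 and adjusted p = 0.0635 with an estimated correlation).

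Of 53 signalosome genes 9 were lower in resting Lat- cells (10 adjusted over the list alone, camera adjusted p = 6.24e-10 and adjusted p = 0.0423 with an estimated correlation). Cd5 differed by -1.42 (SE 0.11, limma adjusted p = 1.24e-05) and Cd6 by -1.24 (SE 0.10, limma adjusted p = 1.64e-05), and the phosphatase-like regulator gene Ubash3b by -1.34 (SE 0.16). Zap70 (-0.09, SE 0.10), Lcp2 (0.03, SE 0.09) and Cd69 (0.37, SE 0.35) were not called (limma adjusted p = 0.862, 0.966 and 0.818). Of 32 negative regulators 6 were lower (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.06e-06 and adjusted p = 0.35 with an estimated correlation). One was the MAP kinase phosphatase gene Dusp4 (-2.52, SE 0.39). Of 25 helper T cell transcription factor genes 8 were lower (12 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.09e-12 and adjusted p = 0.0345 with an estimated correlation). Bhlhe40 differed by -2.06 (SE 0.34) and Id2 by -1.06 (SE 0.09). Of 12 type 2 helper genes 3 were lower (4 adjusted over the list alone, camera adjusted p = 1.88e-06 and adjusted p = 0.026 with an estimated correlation). Gata3 was among these (-0.62, SE 0.10). Of 24 NFAT-linked genes 3 were lower and 1 higher (4 and 1 adjusted over the list alone, camera adjusted p = 7.21e-05 and adjusted p = 0.396 with an estimated correlation). The higher one was the death ligand gene Fasl (0.72, SE 0.13). Of 24 immediate early genes 0 were called at rest (0 adjusted over the list alone, camera adjusted p = 0.605), and without array 1 of resting Lat- cells the list passed camera downward (0.000222). With the replicate number as a block 2 of them were higher and 1 lower, among them Jun (0.71, adjusted p = 0.331 without and 0.0317 with the block).

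Only the ribosome biogenesis and heat shock lists were shifted upward at rest by camera. Of 40 ribosome biogenesis genes 1 was higher (1 adjusted over the list alone, median 0.17, camera adjusted p = 3.14e-08 and adjusted p = 0.392 with an estimated correlation). Of 10 heat shock genes 1 was higher (2 adjusted over the list alone, camera adjusted p = 0.000275 and adjusted p = 0.0635 with an estimated correlation), the co-chaperone gene Bag3 (0.62, SE 0.11). Of 8 CD8 T cell markers 3 were lower (5 adjusted over the list alone, camera adjusted p = 3.39e-06 and adjusted p = 0.026 with an estimated correlation). These included the integrin gene Itgae (-1.68, SE 0.14), which the regulatory list also holds. Of 26 myeloid and dendritic cell markers 2 were lower (2 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0411 and adjusted p = 0.422 with an estimated correlation). That call ended without array 1 or 2 of resting Lat+ cells (0.169 and 0.0504), without array 1 or 2 of resting Lat- cells (0.144 and 0.202) and after quantile normalization (0.0606). Of 19 B cell markers 2 were lower (4 adjusted over the list alone, camera adjusted p = 0.0677, and 0.00329 without array 3 of resting Lat+ cells or 0.000933 without the lowest tercile of genes), among them Cd79b (-0.77, SE 0.13). The differences of Itgae and Cd79b are lower bounds in size, as both lay below every array median in Lat- cells. Bag3 and Cd79b were not called in a fit on the resting groups alone (limma adjusted p = 0.0656 and 0.0664). The remaining lists with a downward call were 26 cytokine and chemokine genes with 3 lower (5 adjusted over the list alone, camera adjusted p = 0.00414 and adjusted p = 0.396 with an estimated correlation; 0.068 without array 1 of resting Lat+ cells) and 18 glycolysis genes with 1 lower (4 adjusted over the list alone, camera adjusted p = 0.00721 and adjusted p = 0.412 with an estimated correlation; 0.226 without array 3 of resting Lat- cells). Of 25 NF-kappaB-linked genes 2 were lower (3 adjusted over the list alone, camera adjusted p = 0.0634, and 0.0195 with the replicate number as a block). Of 13 NK cell markers 1 was lower and 1 higher (4 and 2 adjusted over the list alone, camera adjusted p = 0.147, and 0.0212 with the replicate number as a block).

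Activation of Lat- cells addressed what response was left in cells sorted as lacking Lat. Tnfrsf9 rose at least 22.3-fold (log2 difference 4.48, SE 0.24, limma adjusted p = 6.79e-07), from 4.76 ± 0.22 to 9.24 ± 0.36 (SD, n = 3). Its resting level lay below every array median and was not shown to be above background, so the fold is a lower bound. The epoxide hydrolase gene Ephx1 rose by 1.86 (SE 0.14, limma adjusted p = 1.92e-05), Padi2, an enzyme that converts arginine to citrulline, by 1.73 (SE 0.18) and Sema7a by 1.51 (SE 0.20). Cd5 rose by 1.28 (SE 0.11) and Cd6 by 1.18 (SE 0.10), each with a limma adjusted p of 5.48e-05. The spermidine synthase gene Srm rose by 1.36 (SE 0.13), the kinase gene Map2k6 by 1.35 (SE 0.11), Bcat1 by 1.33 (SE 0.15) and Lgals1, which encodes galectin-1, by 1.03 (SE 0.13). Sema7a, Bcat1 and Il2 also lay below every array median at rest, so their rises are lower bounds too. Lat+ cells in the Lat- sort could add to such rises, and the remaining Lat signal allows a share of 12.8%. Tnfrsf9 would need 12.7%, Sema7a 2.33%, Bcat1 2.08% and Srm 7.90%, all under that share, while Cd5 and Cd6 would need 35.9% and 39.4%. Among the 118 genes raised at least 8-fold in Lat+ cells Tnfrsf9 needs the highest share, and the median is 2.63%. A share of 12.7% would give the others larger rises than measured. Signal near background understates rises of dim genes, so this does not settle the source. Zap70 (0.20, SE 0.10), Lcp2 (0.29, SE 0.09) and Cd69 (-0.07, SE 0.35) were not called (limma adjusted p = 0.649, 0.227 and 0.979). The call of Il2 (0.79, SE 0.19), chosen after its values were seen, depended on the fit: its limma adjusted p was 0.108, 0.0215 with the replicate number as a block (SE 0.14) and 0.0445 without array 3 of activated Lat- cells. In all, limma called 103 genes higher and 13 lower, of which 27 and 0 changed at least 2-fold, and 1584 had an unadjusted p under 0.05.

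The number of genes called in Lat- cells rested on single arrays. It was 194 higher without array 3 of resting Lat- cells and 49 higher without array 1 or without array 3 of activated Lat- cells. The count of lower genes was 2, 4 and 74 without array 1, 2 or 3 of resting and 0, 1 and 3 without array 1, 2 or 3 of activated Lat- cells. Without all 4 arrays numbered 1, a choice made after seeing the data, 33 genes were higher and 0 lower. Of 38 named called genes, 15 kept the call whichever array was left out, among them Tnfrsf9, Cd5, Cd6, Ephx1, Padi2, Sema7a, Srm, Map2k6, Bcat1 and Lgals1. The named lower genes did not. Casc1 (-0.92, SE 0.16, a lower bound in size) had an adjusted p of 0.0206, and 0.0681, 0.0641, 0.121 and 0.0824 without array 1 or 2 of resting or array 1 or 2 of activated Lat- cells. Brca1 (-0.79, SE 0.16), a DNA repair gene, had 0.0433, and 0.127, 0.133, 0.227, 0.0637 and 0.138 without array 1 or 2 of resting or array 1, 2 or 3 of activated Lat- cells, and 0.0504 with the replicate number as a block. Olfr1331, Olfr482 and Olfr1253, olfactory receptor genes with close copies, are uncertain.

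By gene group, activated Lat- cells showed small upward shifts. Of 27 activation surface genes 5 rose (9 adjusted over the list alone, median 0.30, camera adjusted p = 2.02e-10 and adjusted p = 0.306 with an estimated correlation). Of 18 cholesterol biosynthesis genes 3 rose (12 adjusted over the list alone, median 0.43, camera adjusted p = 1.79e-14 and adjusted p = 0.201 with an estimated correlation). Dhcr7, the enzyme of the last step of cholesterol synthesis, was higher by 1.16 (SE 0.13). Of 53 signalosome genes 7 rose (10 adjusted over the list alone, median 0.15, camera adjusted p = 1.85e-09 and adjusted p = 0.201 with an estimated correlation). These included the phosphatase gene Ptpn6 (0.90, SE 0.13). Of 40 ribosome biogenesis genes 1 rose (3 adjusted over the list alone, median 0.23, camera adjusted p = 4.96e-09 and adjusted p = 0.388 with an estimated correlation). Of 24 NFAT-linked genes 2 rose (5 adjusted over the list alone, median 0.40, camera adjusted p = 1.11e-07 and adjusted p = 0.306 with an estimated correlation). Of 24 immediate early genes 0 were called by limma (0 adjusted over the list alone, camera adjusted p = 0.321). That list passed camera downward without array 2 of resting (0.00309) and array 1 of activated Lat- cells (0.000789) and upward without array 1 of resting Lat- cells (0.0238). Of 26 cytokine and chemokine genes 1 rose (4 adjusted over the list alone, camera adjusted p = 0.0623, and 0.0159 and 0.0181 without array 1 of resting or array 3 of activated Lat- cells, 0.0444 without the lowest tercile of genes, or 0.0386 with the replicate number as a block).

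A further 7 lists passed camera in activated Lat- cells, and each lost the call when array 3 of resting Lat- cells was left out. Without array 3 of resting Lat- cells the adjusted p went from 9.82e-05 to 0.0567 for 18 glycolysis genes (0 called; 2 higher adjusted over the list alone), from 0.00029 to 0.0944 for 26 amino acid transport and ATF4-linked genes (0 called; 3 higher adjusted over the list alone) and from 0.000123 to 0.14 for 31 interferon-stimulated genes (0 called; 5 higher adjusted over the list alone). It went from 0.00412 to 0.143 for 17 unfolded protein response genes (0 called; 0 adjusted over the list alone) and from 0.00412 to 0.324 for 16 p53 target genes (0 called; 1 higher adjusted over the list alone). With an estimated correlation the adjusted p of these lists was 0.306, 0.498, 0.239, 0.306 and 0.388, in the same order. For 26 effector and memory markers (2 higher; 2 adjusted over the list alone) it went from 0.00433 to 0.182, and to 0.0761 without array 2 of activated Lat- cells (adjusted p = 0.576 with an estimated correlation). For 15 regulatory T cell markers (1 higher; 3 adjusted over the list alone) it went from 0.0479 to 0.454, and to 0.0594, 0.183 and 0.0609 without array 2 of resting or array 1 or 3 of activated Lat- cells (adjusted p = 0.576 with an estimated correlation). Centring on array medians (0.0551), leaving out the lowest tercile of genes (0.074) and the replicate block (0.0549) ended this call too. With that block 3 of the ATF4-linked genes, 2 of the interferon-stimulated genes and 1 of the p53 target genes were called higher, among them Psat1 (adjusted p = 0.0135), Usp18 (0.0172) and Phlda3 (0.0296).

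After activation, Lat- and Lat+ cells differed over much of the transcriptome. Il2 was at least 93.7-fold lower in Lat- cells (log2 difference -6.55, SE 0.19, limma adjusted p = 3.52e-11), Ccl3 at least 71.6-fold lower (-6.16, SE 0.24) and Xcl1 41.5-fold lower (-5.37, SE 0.18). Irf8 (-5.26, SE 0.17), Spry1 (-5.21, SE 0.34) and the ligand gene Tnfsf14 (-5.01, SE 0.17) were also lower. Ccl3 (4.73) and Tnfsf14 (4.30) lay below every array median in Lat- cells, as did Il2 on array 3 (5.21), so these 3 differences are lower bounds in size. Higher in Lat- cells were Il7r (3.59, SE 0.19), S1pr1 (3.48, SE 0.11), Itga6, an integrin chain (3.07, SE 0.09), and Pik3ip1 (3.24, SE 0.13). Cd5 (-1.45, SE 0.11), Cd6 (-1.30, SE 0.10), Zap70 (-1.38, SE 0.10), Lcp2 (-0.45, SE 0.09) and Cd69 (-1.54, SE 0.35) were all lower. In all, limma called 3778 genes higher and 3621 lower, of which 1120 and 1391 differed at least 2-fold.

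All 24 NFAT-linked genes (24 adjusted over the list alone, camera adjusted p = 9.84e-16 and adjusted p = 0.0781 with an estimated correlation), all 40 ribosome biogenesis genes (40 adjusted over the list alone, camera adjusted p = 5.97e-30 and adjusted p = 0.0781 with an estimated correlation) and all 27 activation surface genes (27 adjusted over the list alone, camera adjusted p = 4.42e-18 and adjusted p = 0.0826 with an estimated correlation) were lower in activated Lat- than in activated Lat+ cells. Of 28 genes of naive and quiescent cells 25 were higher (26 adjusted over the list alone, camera adjusted p = 1.05e-13 and adjusted p = 0.0781 with an estimated correlation). Of 15 regulatory T cell markers 14 were lower and 1 higher (14 and 1 adjusted over the list alone, camera adjusted p = 2.21e-07 and adjusted p = 0.108 with an estimated correlation). Lrrc32 differed by -3.96 (SE 0.42) and the CD25 gene Il2ra by -3.40 (SE 0.31). Of 30 cell cycle genes 20 were lower and 3 higher (20 and 3 adjusted over the list alone, camera adjusted p = 2.41e-06 and adjusted p = 0.0781 with an estimated correlation). Cdk6 differed by -3.48 (SE 0.16). Of 12 type 2 helper genes 5 were lower (5 adjusted over the list alone, camera adjusted p = 0.018 and adjusted p = 0.172 with an estimated correlation). Il10 was among these (-2.24, SE 0.29). The call for this list ended without array 1 of activated Lat+ cells (0.0653) and without the lowest tercile of genes (0.118). Of 19 B cell markers 6 were lower (6 adjusted over the list alone), and the list had no camera call (adjusted p = 0.145). The 6 included the MHC class II invariant chain gene Cd74 (-2.20, SE 0.30) and H2-Aa (-1.79, SE 0.24). The differences of Il10, Cd74 and H2-Aa are lower bounds in size, since their levels in Lat- cells lay below every array median.

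The difference between both activation responses was tested directly. The rise of Irf8 was smaller in Lat- cells (log2 difference between responses -4.93, SE 0.24). The measured rises of Ccl3 (-5.76, SE 0.34, limma adjusted p = 2.46e-08) and Il2 (-5.70, SE 0.28, limma adjusted p = 7.34e-09) differed too, but both genes lay below every array median in resting Lat- cells, and Ccl3 also in resting Lat+ and activated Lat- cells. The true size of these 2 differences is therefore not known. The falls of S1pr1 (3.54, SE 0.15) and Il7r (3.51, SE 0.26) were smaller in Lat- cells as well. Zap70 (-1.29, SE 0.15, limma adjusted p = 8.12e-06), Lcp2 (-0.47, SE 0.12, limma adjusted p = 0.00708) and Cd69 (-1.91, SE 0.49, limma adjusted p = 0.0076) responded less in Lat- cells. The responses of Cd5 (-0.04, 95% interval -0.37 to 0.30), Cd6 (-0.06, -0.37 to 0.25) and Tnfrsf9 (0.36, SE 0.34) were not called different (limma adjusted p = 0.904, 0.815 and 0.485). Tnfrsf9 was chosen here after its values were seen, and its rise in Lat- cells is a lower bound, so equal responses are not shown. In all, 2984 genes had a difference above 0 and 2828 below 0.

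By group, 39 of 40 ribosome biogenesis genes had a difference called below 0 (40 adjusted over the list alone, camera adjusted p = 3.38e-34 and adjusted p = 0.117 with an estimated correlation), as did 19 of 24 NFAT-linked genes (20 adjusted over the list alone, camera adjusted p = 7.19e-13 and adjusted p = 0.121 with an estimated correlation). Of 26 cytokine and chemokine genes 16 did (17 adjusted over the list alone, camera adjusted p = 3.14e-09 and adjusted p = 0.118 with an estimated correlation). Of 27 activation surface genes 18 did (18 adjusted over the list alone, camera adjusted p = 3.14e-09 and adjusted p = 0.264 with an estimated correlation). Of 28 naive and quiescence genes 23 were above 0 (23 adjusted over the list alone, camera adjusted p = 7.86e-15 and adjusted p = 0.0809 with an estimated correlation). Of 53 signalosome genes 27 were above 0 and 10 below (28 and 11 adjusted over the list alone, camera adjusted p = 0.00232 and adjusted p = 0.325 with an estimated correlation), Fyb (2.39, SE 0.18) and Grap2 (1.87, SE 0.13) among those above. Of 32 negative regulators 16 were below 0 and 6 above (17 and 7 adjusted over the list alone, camera adjusted p = 0.0482 and adjusted p = 0.654 with an estimated correlation). That call ended without array 2 or 3 of resting Lat+ (0.0768 and 0.065), array 1 of activated Lat+ (0.0801), array 1 of resting Lat- (0.119) and array 2 or 3 of activated Lat- cells (0.0956 and 0.05), after quantile normalization (0.138), after centring on array medians (0.0554) and without the lowest tercile of genes (0.128). A list's median, mean and camera direction differed in sign only for lists without a call: hypoxia genes in all 5 comparisons, cell cycle genes in both activations and their difference, gamma-delta markers after activation and in the difference, immediate early, RAS-MAPK feedback, naive and CD8 lists in activated Lat- cells, the ATF4-linked and unfolded protein response lists at rest, and erythroid markers after activation.

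**Figure D2:**
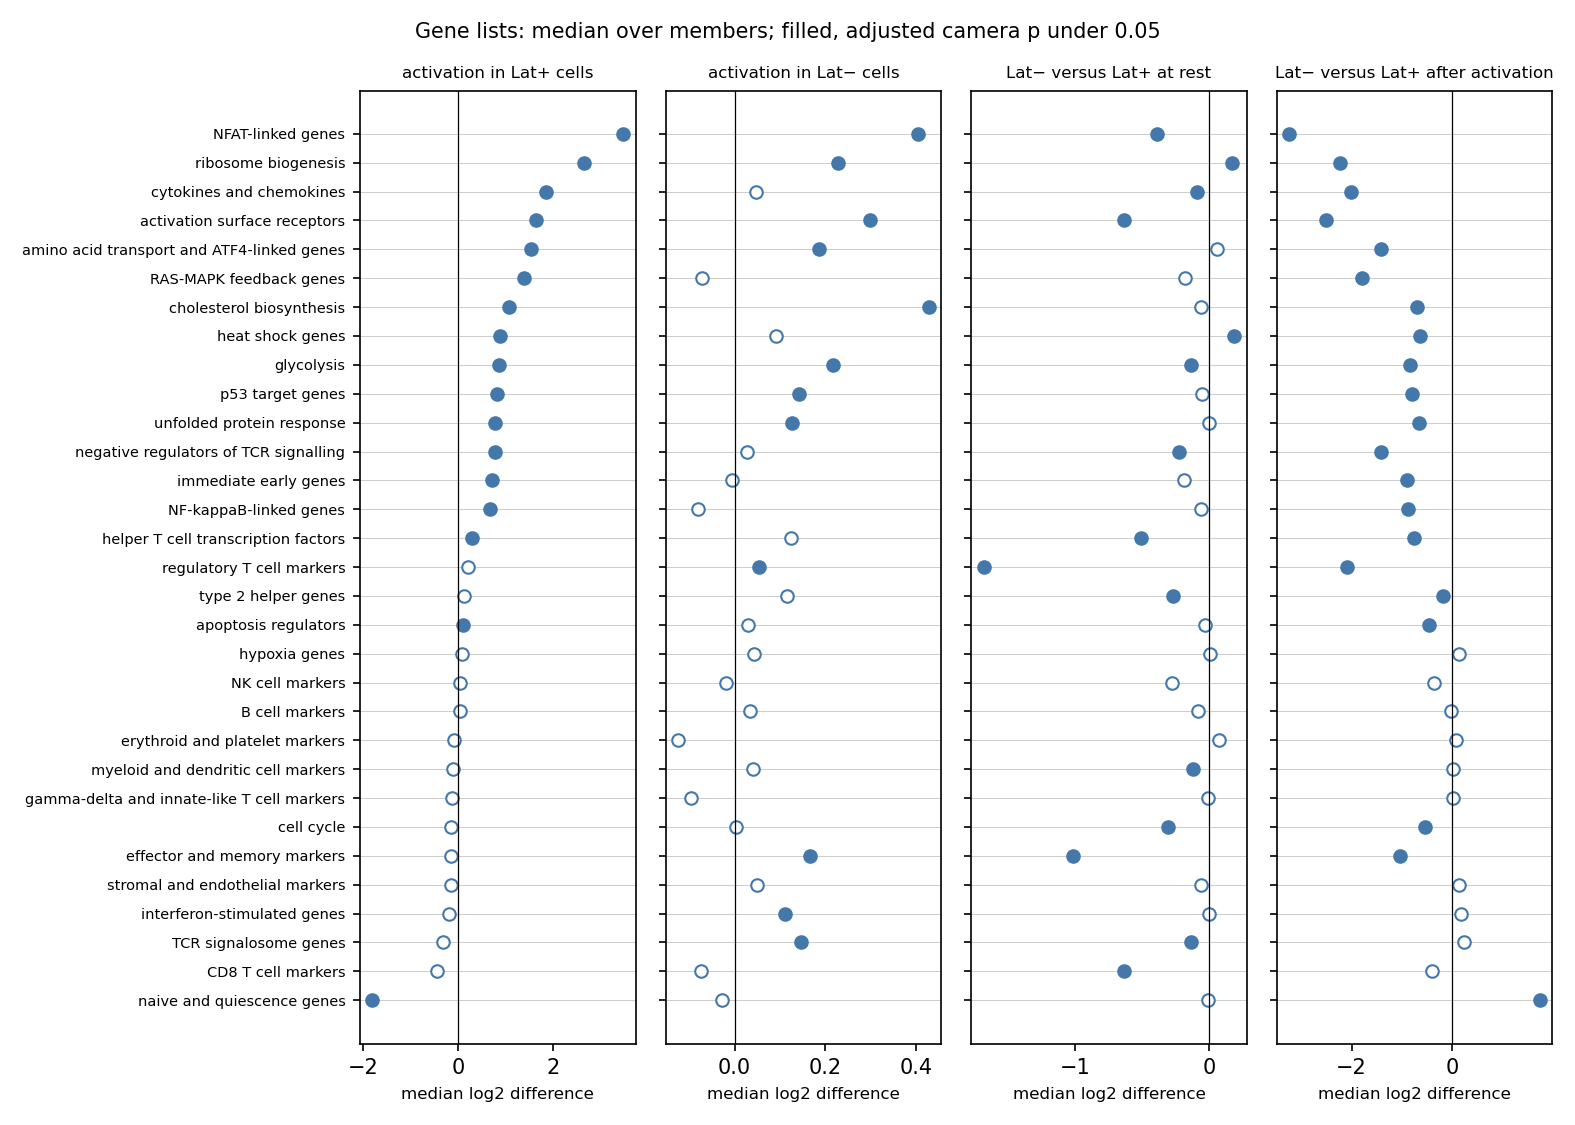
Median log2 difference of the members of each gene list (horizontal axis, whose scale differs between the 4 panels) in the 4 comparisons between groups; filled points passed camera at an adjusted p under 0.05. Ribosome biogenesis genes have a median of 2.67 in activated Lat+ and 0.23 in activated Lat- cells, and regulatory T cell markers have a median of -1.68 in Lat- against Lat+ cells at rest.

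Set against each other over genes, the change in Lat- cells was small beside that in Lat+ cells, and it ran along with it mainly for raised genes. Over the 2723 genes that changed at least 2-fold in Lat+ cells, the slope of the Lat- change on the Lat+ change was 0.0654 and the median ratio 0.0416, with quartiles of -0.0343 and 0.118. Over the 1454 raised genes the slope was 0.102 and the median ratio 0.0636, while over the 1269 lowered genes they were 0.00779 and 0.0146. The slope of the lowered genes rested on single arrays: it was 0.019, -0.0195 and 0.0239 without array 1, 2 or 3 of resting Lat- cells, 0.0171 after quantile normalization and 0.00317 after centring on array medians. Genes are not independent replicates, so these are descriptions, and the difference between both directions was not tested. For 2672 of the 2723 genes (98.1%) the change was smaller in Lat- cells with the difference called. Over all 7369 genes called in Lat+ cells this held for 5590 (75.9%). Both activations called 66 genes higher, against 19.1 for independent lists of these sizes, and 6 lower, against 2.68. The numbers for independent lists are lowered by dim genes, which are seldom called in either activation, so part of the excess may reflect level alone. Of these 72 genes, 51 had a smaller change in Lat- cells with the difference called, and for 21 the difference was not called, Cd5, Cd6 and Tnfrsf9 among them. The count of 72 was 28 without array 1 or without array 3 of activated Lat- cells, and 27 without the 4 arrays numbered 1.

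**Figure D3:**
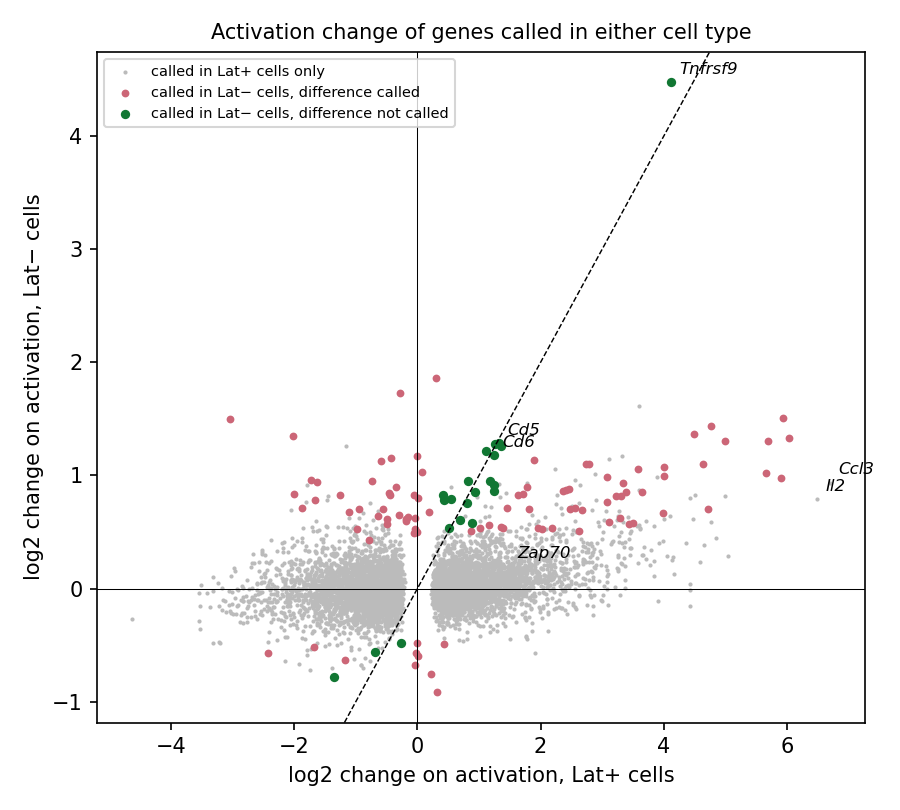
Log2 change on activation in Lat+ cells (horizontal) against that in Lat- cells (vertical), 1 point per gene called in either activation, coloured by where the change was called; the dashed line marks equal change. Tnfrsf9 (4.11 and 4.48), Cd5 (1.32 and 1.28) and Cd6 (1.24 and 1.18) lie near that line, while Il2 (6.49 and 0.79) and Zap70 (1.49 and 0.20) lie far below it; the changes of Tnfrsf9 and Il2 in Lat- cells are lower bounds.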

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

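The tests of Lat+ cells in the Lat- sort and the regroupings within pairs were chosen only after the result was seen. The test of 1 common share of Lat+ cells was also changed after an earlier run. The direct test of both activation responses found a difference above 0 for 2984 genes and below 0 for 2828 (limma, adjusted p under 0.05), so the responses of Lat+ and Lat- cells differed for these genes. Of 100 regroupings of the arrays by genotype within each condition, 3 called as many genes as the real 5812, the real one included, and the highest other called 6608. That share lies under 0.05, but these regroupings ignore the same-numbered pairs. Of the 32 that swap genotype only within pairs, 4 called as many, the real one included, and the highest other called 6767. The 8 of them that kept the genotype split of the activated arrays called at least 5329 genes, and those that regrouped the activated arrays called at most 1. Since these 8 keep most of the difference, the share of 4 in 32 decides nothing about chance. The count therefore follows the grouping of the activated arrays.

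For the 4 comparisons between groups, 3 arrays against 3 allow 10 splits, which are too few for a share under 0.05. In each, 1 split, the real one, gave a count as large. The real count and the highest other were 7369 and 0 for activation in Lat+ cells, 116 and 1 for activation in Lat- cells, 369 and 2 at rest, and 7399 and 0 after activation. In each of the 4, the 3 other splits that part all same-numbered pairs called 0 genes.

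Activation moved 24 genes in opposite directions in Lat+ and Lat- cells, which drew attention because both changes were called by limma. Of these, 23 rose in Lat- and fell in Lat+ cells, against 21.2 for independent lists of these sizes. They included Map2k6, a kinase that activates p38 (-2.02 in Lat+ and 1.35 in Lat- cells), Tgfbr3, a co-receptor for TGF-beta (-2.00 and 0.83), and the fatty acid oxidation gene Hadh (-1.74 and 0.96). The fall of Map2k6 is a lower bound in size, since its level in activated Lat+ cells lay below every array median. These 3 were chosen after their values were seen. Of the 23 genes, 12 were also called lower at rest in Lat- than in Lat+ cells, among them Map2k6 (-1.19) and Hadh (-0.66). Both comparisons use the same resting Lat- arrays, so part of these rises may come from those arrays. Dim genes, seldom called in either activation, lower the number of 21.2 for independent lists.

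Signal was also present in probe sets outside the tested genes. Activation of Lat+ cells raised 336 and lowered 310 of 1881 probe sets with several gene symbols, and raised 1264 and lowered 1245 of 12457 probe sets that the annotation does not list (limma). Their genes were not named here.

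Tnfrsf9, Cd5 and Cd6 are among the genes higher in both activations whose difference was not called, and Lat+ cells in the Lat- sort could raise such genes. The share of Lat+ cells that the rises would need had a median of 58.8% over 18 genes (quartiles 41.2% and 77.8%). The Lat signal left in Lat- cells at rest allows 12.8%, with an upper bound of 17.0%. These 18 were picked for a difference that was not called, which favours high shares, so the gap does not test this source. The 48 genes higher in both activations with the difference called would need a median of 8.57% (quartiles 5.41% and 13.9%), under that bound. Tnfrsf9 alone would need 12.7%, under the bound of 17.0%. That is the highest share among the 118 genes raised at least 8-fold in Lat+ cells, whose median was 2.63% (quartiles 1.32% and 5.04%). Over these 118 genes, 34 lay outside the interval of 1 common share of Lat+ cells, fitted at 2.5%. Simulated data gave a median of 6 and a highest of 13. The simulated genes varied independently and only the error of the Lat- change was drawn, so these draws may give too few genes outside. The comparison therefore does not decide whether Lat+ cells gave the whole response. Cd5 and Cd6 were named by the rule fixed in advance, not picked for that difference, and would need 35.9% and 39.4%. The shares assume cells that respond like the Lat+ sort. Both lie above the bound of 17.0%, which argues against Lat+ cells as the only source of these 2 rises. For the other genes Lat+ cells in the Lat- sort stay open as a source, alone or beside a response of Lat- cells.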

How the results depend on the processing

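The fits without all 4 number-1 arrays and the slopes by direction were chosen only after the data were seen. Of the alternatives' values, 261 counts and slopes stayed within the limits set for them and 51 moved. Among gene list tests 1850 kept their direction and side of the threshold, 136 lost a call, 51 gained one and 4 reversed. Named genes kept theirs in 7966 tests, lost a call in 307 and gained one in 41. With 3 arrays per group, counts of genes near the threshold are the least stable, and low array signal lies close to background, which limits dim genes.

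Array weights left 8 genes lower in activated Lat- cells. A fit on only the compared groups gave 48 higher and 0 lower for activation in Lat- cells, 12 higher and 198 lower at rest, and 32 genes shared by both activations. Fewer arrays enter that fit. At a change of at least 2-fold the counts higher and lower were 1454 and 1269 for activation in Lat+ cells, 27 and 0 in Lat- cells, 5 and 135 at rest, 1120 and 1391 after activation, 1322 and 1344 for the difference, with 19 shared. At an adjusted p under 0.01 they were 40 and 0 for activation in Lat- cells, 13 and 195 at rest, with 23 shared. Without the number-1 arrays they were 33 and 0 for activation in Lat- cells, 8 and 172 at rest, with 27 shared, from fewer arrays.

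Camera with an estimated correlation called 0 lists in activated Lat+ cells, 0 in activated Lat- cells, 7 at rest, 0 after activation and 0 for the difference. Fry called 2 lists in activated Lat- cells. Under fry the hypoxia list reversed, with adjusted p = 7.67e-05 downward in activated Lat+ cells, 0.001 upward after activation and 0.00049 upward for the difference. Fry weighs a list's genes without setting them against other genes, and the cause was not tested.

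Leaving out 1 array at a time gave 3202 to 3336 genes higher and 3493 to 3594 lower for activation in Lat+ cells, 49 to 194 and 0 to 74 for activation in Lat- cells, 15 to 163 and 207 to 396 at rest, 3309 to 3674 and 3279 to 3499 after activation, and 2714 to 3545 and 2561 to 3103 for the difference. The shared count ran from 28 to 100 and the slope from 0.0504 to 0.0846. Over raised genes it ran from 0.0715 to 0.127. Over lowered genes it ran from -0.0195, reversed without array 2 of resting Lat- cells, to 0.0239, without array 3, and the cause was not tested. Lists called ran from 16 to 17, 6 to 18, 13 to 19, 20 to 21 and 16 to 19, in the same order. Immediate early genes in activated Lat- cells reversed without array 1 of resting Lat- cells (camera adjusted p = 0.0238 upward), and over the arrays left out its adjusted p ran from 0.000789 (downward, without array 1 of activated Lat- cells) to 0.564. The number-1 arrays had the higher level of these genes, so leaving 1 of them out shifts that group's mean.

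The replicate block called 7627 genes in activated Lat+ cells (7305 shared with the fit without it), 169 in activated Lat- cells (109 shared), 496 at rest (358 shared), 7699 after activation (7331 shared) and 6245 for the difference (5756 shared). It moved 1 count by over 1.5 times, to 67 genes higher at rest. It ended the calls of Il23r in activated Lat+ cells (adjusted p = 0.0636) and of Brca1 (0.0504), Bcl2 (0.0517), 1700029H14Rik (0.0537), Spdl1 (0.0582) and the regulatory list (0.0549) in activated Lat- cells. It gave calls to Il2 (0.0215), Psat1 (0.0135), Usp18 (0.0172), Igfbp4 (0.0209), Phlda3 (0.0296), Ccr4 (0.0363) and the cytokine list (0.0386) in activated Lat- cells, and at rest to Car2 (0.00597), Jun (0.0317), Irf9 (0.0393) and the NF-kappaB-linked (0.0195) and NK cell (0.0212) lists. It changed no other call of a list or named gene. Of 3 arrays each, 3 correlated best with their own number for activation in Lat- cells and 1 at rest.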

Other observations

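The tests of overlap, of the T cell markers and of the number-1 arrays were chosen only after the result was seen. That of signalling through Lat before the culture was also changed after an earlier run. Some genes that were low in resting Lat- cells rose when these cells were activated. Limma called 38 genes both lower at rest in Lat- than in Lat+ cells and higher on activation of Lat- cells, against 1.82 for independent lists of these sizes. They included the epoxide hydrolase gene Ephx1 (-1.87 at rest and 1.86 on activation), Padi2 (-0.82 and 1.73), Tnfrsf9 (-3.37 and 4.48), Cd5 (-1.42 and 1.28) and Cd6 (-1.24 and 1.18). Both values of Tnfrsf9 are lower bounds in size, since its resting level in Lat- cells lay below every array median. Both comparisons use the same resting Lat- arrays, so part of the excess may come from these arrays, which cannot be halved with enough arrays in each part. Dim genes, seldom called in either comparison, also lower the number of 1.82 for independent lists. Over all genes the covariance of both changes was -0.0190, against -0.00928 in 50 simulated draws without effects, a difference of -0.00973. The draws held no link between same-numbered arrays, which could change the simulated value. The correlations were -0.449 observed and -0.501 simulated. The count of genes lower at rest was 207 without array 2 of resting Lat+ cells.

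Markers of regulatory and effector T cells were lower in resting Lat- cells, and a smaller share of such cells in the Lat- sort is a candidate explanation. For 12 markers that activation of Lat+ cells did not move, the difference after activation was 0.992 times that at rest in the median, which decides nothing, since markers unmoved in Lat+ cells were picked and activation of Lat- cells moved 0 of the 12 in the fit without the replicate block (with it Il2rb was called higher), which holds the ratio near that value. The sort took CD25-, CD62L+ cells, a gate that would remove CD25+ regulatory and CD62L- effector cells, and 8 of the 15 regulatory markers are also in another list. Less signalling through Lat before the culture stays open: of 1266 genes that activation of Lat+ cells raised at least 2-fold and that are in no list, 3.56% were lower at rest, against 1.25% of other genes, but their median difference was 0.04 (camera p = 0.743 with an estimated correlation). Both explanations stay open.

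Immediate early genes were higher on the number-1 arrays of the 3 groups other than activated Lat+ cells, by 0.95, 1.05 and 0.97. The number-1 arrays carried both Xist (9.25 to 9.84) and the Y-linked gene Eif2s3y (8.22 to 8.51), the number-2 arrays Eif2s3y alone and the number-3 arrays Xist alone, in all 4 groups. Sex of the mice would place the mixed array between the others, which held in 0 of 3 groups, and this argues against it. Stress that raises heat shock genes would lift that list as well, whose highest rise was 0.0980, which argues against it too. Handling time and other causes that spare heat shock genes were not tested.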
